A study of Mus musculus with 5 samples.

How the data were processed

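RNA from 5 mouse samples was amplified, labelled with Cy5 and hybridised to 1 single-colour array each, per the labels' protocols: 1 array of mock-transduced embryonic fibroblasts (MEF), 2 of fibroblasts transduced with Dmrt1, Gata4 and Nr5a1 (iLC) and 2 of Leydig cells isolated from testes of 56-day-old mice. Per the labels' protocols, fibroblasts came from embryos of 13.5 days, were exposed to lentivirus for 12 hours and then kept in a medium to which IGF had been added at 50 ng/ml and PDGFAA at 10 ng/ml; the same protocol text stands beside every sample, so whether the mock-transduced cells were moved to that medium, and for how long iLC were cultured, is not given in the sources used here. Samples were grouped by their titles and cell type labels. The labels also carry short codes whose meaning is not given, and these were not used. The codes differ between the 2 iLC arrays and between the 2 Leydig arrays, which were taken as replicates by their titles, and every spread rests on these pairs.

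The deposited values are probe intensities on a linear scale, as the authors processed them; their background correction, normalization and software are not given in the sources used here. Detection calls and spot flags were not used here, so no signal over background could be set for a probe. The arrays had close medians, 1111 to 1230, without identical distributions. Values under 600 were whole multiples of a step of its own on each array (100% within a tolerance of 0.02 steps, against 0% between 1200 and 5000), with steps of 0.841 to 1.13 intensity units. The low ends differed: the smallest value was 48.0 on the MEF array, -47.3 and -18.6 on the iLC arrays, and 4.10 and -37.8 on the Leydig arrays, and 0, 435, 23, 0 and 46 values lay below 0. A dim probe can therefore differ between arrays by its array's offset alone.

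Probes were named through the platform annotation paired with the table. Of 26423 probes, 21876 had 1 gene symbol, 0 had several and 4547 had none. Of the named probes, 21825 had an Entrez identifier in a reference gene table (assembly GRCm38.p6, used for names only), and 0 of these had another symbol there. No coordinates were used. For the 2424 genes with more than 1 probe, the probe with the highest mean over the 5 arrays was used, giving 19084 genes. Another probe of the gene went the same way for 6 of 7 called genes with several probes between iLC and MEF, 212 of 244 between iLC and Leydig cells, and 136 of 149 between Leydig cells and MEF. 0 columns of the table belonged to no sample.

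Values were taken to log2 after adding 16. The planned transformation could not take values more than 16 below 0, of which there were 187, 1 and 6 on 3 arrays, so values below 0 were set to 0 first. Differences are on the log2(value + 16) scale, where the added 16 shrinks those of dim genes. Unequal low ends can also enlarge or create differences of dim genes. The 1st percentile was 83.8 on the MEF array and -10.1 and 23.7 on the iLC arrays. The linear model of limma 3.58.1 in R 4.3.3 was fitted with 1 mean per group over all 5 arrays (lmFit, eBayes), and Benjamini-Hochberg adjustment was made over the 19084 genes of each comparison, with a threshold of 0.05; tests were two-sided. The fit had 2 residual degrees of freedom and 4.21 prior degrees of freedom. Root mean square standard deviations between paired arrays were 0.459 for iLC and 0.548 for Leydig cells, on the log2 scale. The lone MEF array was assumed to vary like these pairs. The word called below means an adjusted p under the threshold.

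27 gene lists for steroidogenic, gonadal, fibroblast and other cell types and pathways were fixed before the data were examined. Each was tested in the 3 comparisons with limma's camera at a preset correlation of 0.01, adjusted over the 81 tests. Of 41 calls, 0 held with a correlation estimated from the 2 residual degrees of freedom, and 27 were also calls of fry, which tests whether a list's genes move one way on balance; 14 were not. Fry gave 35 calls among the 81 tests. With an estimated correlation the lowest adjusted p of the 81 tests was 0.277. The interferon list between iLC and Leydig cells, with 17 of 19 genes lower, had that value too. The values with an estimated correlation printed below therefore do not tell one list from another. Named genes were, by a rule also fixed then, the 3 factors, all measured members of the steroid hormone and adult Leydig lists, the 10 largest called differences in each direction whose groups did not overlap (leaving out predicted genes, clones, olfactory and vomeronasal genes and pseudogenes), and up to 4 called members of each other list with the largest differences, or members with their values where none was called. Other genes were named after their values were seen: where a count or list is spelled out (Cyp11b1, Mki67, Tk1 and Nr4a1, the Hoxd members, steroid genes between Leydig cells and MEF, and others marked so in the text).

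Simulated data had each gene's mean over the 5 arrays in every group, spreads drawn from limma's prior and 200 of 19084 genes changed. The fit of iLC against MEF recovered 0%, 2%, 70% and 96% of genes changed by 1, 2, 4 and 6 log2 units. That of iLC against Leydig cells recovered 0%, 12%, 82% and 100%. False calls numbered 4 and 5. The real group differences were left out, and the data gave 2170 calls between iLC and Leydig cells, so these shares need not hold there. The same spreads were used for simulated iLC arrays without change from MEF. Spreads from each gene's shrunken estimate, tried before these, gave a covariance of 0.17 between the comparisons sharing the MEF array, below the mean residual variance of 0.255, and were replaced after the results were seen. They gave on average 1.12 genes called in the same direction in iLC and Leydig cells, 0.28 above both groups and 0.7 below both. The spreads drawn from the prior gave 0.249. Alternatives planned before the data were examined were quantile normalization, centring of each array, 2 filters on dim genes, a floor at the 20th percentile (220.8), the mean of a gene's probes, an intensity trend, a fold minimum of 2, the 4 iLC and Leydig arrays alone, a replicate block, leaving out each iLC and Leydig array, 2 other list tests and a stricter axis. A larger added value, subtraction of each array's 1st percentile, a robust prior, the 3 MEF and iLC arrays alone, and leaving out genes dark on 1 array were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.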

Results

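Transcript levels were measured on 5 single-colour mouse microarrays. The MEF group is 1 array of fibroblasts grown from mouse embryos of 13.5 days and transduced with a mock vector. The iLC group is 2 arrays of such fibroblasts after lentiviral delivery of Dmrt1, Gata4 and Nr5a1, 3 transcription factors of the gonads, labelled by the submitters as induced Leydig-like cells. The Leydig group is 2 arrays of Leydig cells, the androgen-producing cells between the seminiferous tubules, isolated from testes of mice aged 56 days. Each array held 26423 probes, of which 21876 named a gene, and 1 probe was used for each of 19084 genes. Median probe intensities were 1144 on the MEF array, 1157 and 1215 on the iLC arrays and 1111 and 1230 on the Leydig arrays. Across genes, which are not independent replicates, log2 values correlated at 0.978 between the iLC arrays and 0.962 between the Leydig arrays. The MEF array correlated with the iLC arrays at 0.939 and 0.942 and with the Leydig arrays at 0.899 and 0.875. The iLC and Leydig arrays correlated at 0.876 to 0.906. The MEF group had no replicate, so its spread was taken from the iLC and Leydig pairs. Nothing in the labels says that paired arrays came from separate cultures or animals, so the p-values measure the spread between these arrays only. The number of arrays limits the precision of every value.

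The 3 delivered factors were examined first. Gata4 read 6773 on the MEF array, 4127 and 3150 on the iLC arrays, and 71888 and 50891 on the Leydig arrays. Nr5a1, the master regulator of steroidogenic cells, read 1265 on the MEF array, 1509 and 1158 on the iLC arrays, and 68030 and 44721 on the Leydig arrays. Dmrt1 was dim throughout, at 396.6 on the MEF array, 333.2 and 427.2 on the iLC arrays, and 548.8 and 518.7 on the Leydig arrays. None of the 3 passed the limma test between iLC and MEF, with log2 differences of -0.91 ± 0.43 (SE) for Gata4, 0.06 ± 0.44 for Nr5a1 and -0.07 ± 0.38 for Dmrt1. Gata4 and Nr5a1 were lower in iLC than in Leydig arrays, by log2 differences of -4.06 (adjusted p = 0.00188) and -5.37 (adjusted p = 0.00109). Whether these probes lie inside the delivered sequences is not given in the sources used here, so the readings do not check the labels, and iLC below means the arrays labelled iLC.

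**Figure D1:**
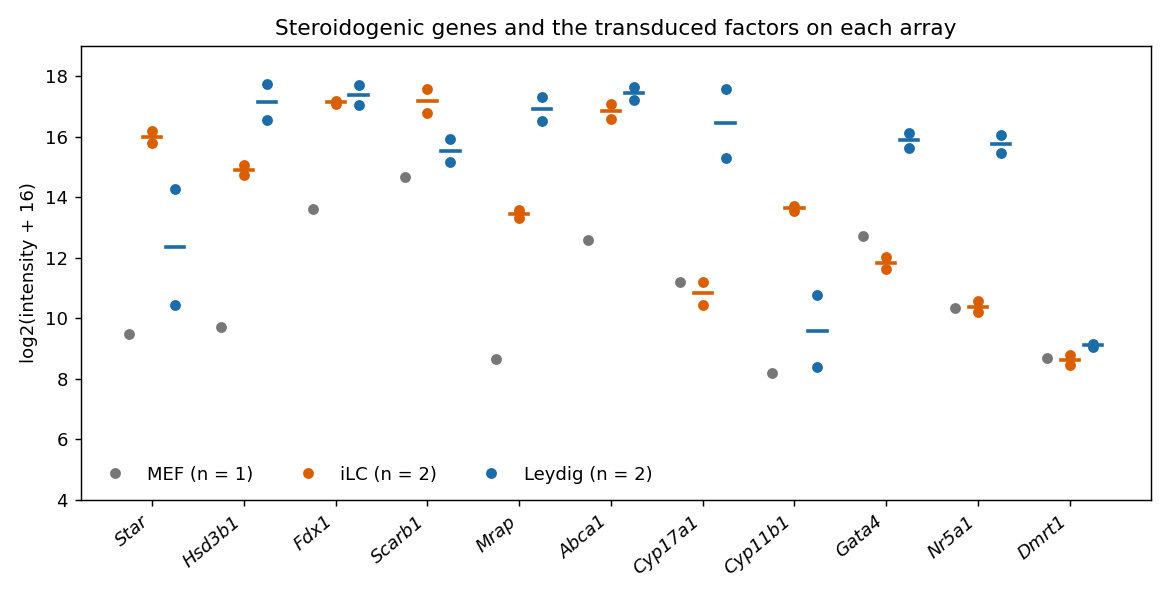
Expression of 8 genes of steroidogenic cells and the 3 delivered factors, as log2 of intensity plus 16 on the y axis, for the MEF array (grey), the iLC arrays (orange) and the Leydig arrays (blue). Points are arrays and bars are means of 2 arrays; Star read 56878 and 73892 on the iLC arrays against 695.0 on the MEF array, while Cyp17a1 read 1382 and 2351 on the iLC arrays against 2344 on the MEF array.

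The comparison of iLC with MEF asked what distinguishes fibroblasts given the factors from mock-transduced fibroblasts. Whether these groups also differed in medium or culture time is not given. Of the measured genes of steroid hormone synthesis, Hsd3b1 and Fdx1 were higher in iLC and the other 7 did not pass the test. Hsd3b1, the enzyme that converts pregnenolone to progesterone, read 829.9 on the MEF array and 27160 and 34513 on the iLC arrays, a log2 difference of 5.18 ± 0.56 (SE, adjusted p = 0.033). Fdx1, the electron donor of the mitochondrial steroidogenic P450 enzymes, was higher by 3.53 ± 0.43 (adjusted p = 0.0388). Star, which carries cholesterol into mitochondria, had a log2 difference of 6.51 ± 1.39 that did not pass (adjusted p = 0.107), with a spread set by the Leydig arrays, where it read 1368 and 19703; its other probe gave 4.15. Scarb1, a cholesterol uptake receptor, had a difference of 2.53 (adjusted p = 0.0992) and Cyb5a, a cofactor of androgen synthesis, one of 1.58 (adjusted p = 0.169). Cyp11a1 (0.39), Cyp17a1 (-0.38), Hsd17b3 (-0.32) and Tspo (0.55) did not pass, and Cyp11a1 stayed at 907.1 or lower on every array. On the Leydig arrays Cyp11a1 read 509.8 and 450.6, against 562.1 on the MEF array, and Hsd17b3 1124 and 3680, against 2165. Neither probe read higher on both Leydig arrays than on the MEF array, so neither can show whether its gene was induced in iLC. Of the 9 measured members of the steroid hormone list, 2 were higher over all genes tested and 5 when adjusted over the list alone. The list's median was 1.58, or 1.69 above that of all genes, and camera gave adjusted p = 1.83e-05, against adjusted p = 0.277 with an estimated correlation. No list in any comparison had a lower adjusted p with an estimated correlation. Of the adult Leydig markers, Sult1e1 and Ptgds differed by 4.82 and 6.02 without passing (adjusted p = 0.339 and 0.318), as both iLC and Leydig pairs were far apart for them, and Hsd11b1 differed by 0.25. The adult Leydig list had a camera adjusted p = 0.121. Between Leydig cells and MEF 0 of its 4 measured members passed over all genes either (median 3.23, camera adjusted p = 0.0476). That list call was lost under 10 of 17 alternatives. These markers can therefore hardly show whether iLC took up an adult Leydig state. Insl3, Lhcgr, Hsd3b6 and Prlr had no named probe. Hsd3b1 and Fdx1 lost their calls without any 1 of the 4 iLC and Leydig arrays, as did every gene called between iLC and MEF. Leaving out an array takes 1 of the 2 residual degrees of freedom, so such losses do not single out a gene.

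Mrap and Abca1 were also higher in iLC. Mrap, the accessory protein of the ACTH receptor, differed by 4.80 ± 0.46 (SE, adjusted p = 0.0281), and Abca1, a cholesterol exporter, by 4.25 ± 0.43 (adjusted p = 0.0281). Cyp11b1, the adrenal 11-beta-hydroxylase, read 274.9 on the MEF array and 13429 and 12027 on the iLC arrays without passing between these groups. Of the 6 fetal Leydig and adrenal markers, 1 was higher and 3 when adjusted over the list alone (median 1.32, camera adjusted p = 9.07e-05; adjusted p = 0.284 with an estimated correlation). Abca1 was the 1 called member of the 10 lipid droplet and cholesterol ester genes (median 0.32, camera adjusted p = 0.0142; adjusted p = 0.323 with an estimated correlation), a call also lost with the stricter filter on dim genes, the floor and aligned low ends. None of the 8 granulosa markers passed, although Amhr2, the receptor of anti-Müllerian hormone, differed by 3.78 (adjusted p = 0.0902) and Inha, the inhibin alpha subunit, by 2.26 (adjusted p = 0.0752). The granulosa list had a median of 0.57 (camera adjusted p = 0.0033; adjusted p = 0.491 with an estimated correlation). None of the 15 gonadal regulators passed, with 2 higher and 2 lower when adjusted over the list alone (median -0.09, camera adjusted p = 0.563), Tcf21 differing by -2.12 and Dhh by 2.02. None of the 14 xenobiotic and antioxidant genes passed singly and 9 did when adjusted over the list alone, Nqo1 (3.03) and Sod3 (2.55) having the largest differences (median 1.56, camera adjusted p = 2.3e-09; adjusted p = 0.277 with an estimated correlation). The p53 and senescence list (median 0.78) and the unfolded protein response list (median 0.49) had no member past the test over all genes and 4 members each when adjusted over the list alone, with Perp (3.61) and Trib3 (2.44) leading. Camera gave them adjusted p = 1.88e-05 and 0.00758, against adjusted p = 0.277 and 0.322 with an estimated correlation. The unfolded protein response call was also lost with the stricter filter on dim genes and with aligned low ends. Mrap and Abca1 lost their calls without any 1 of the 4 iLC and Leydig arrays, as did every gene called in this comparison.

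Several cell division transcripts were lower in iLC than in MEF. Of 22 measured cell cycle genes, 6 were lower over all genes tested and 20 when adjusted over the list alone, and none was higher. The mitotic kinase gene Bub1 had a log2 difference of -4.31 ± 0.49 (SE, adjusted p = 0.0334), Aurka -3.63 ± 0.38 (adjusted p = 0.033), the mitotic kinesin gene Kif11 -3.49 ± 0.45 (adjusted p = 0.0425) and Birc5, also called survivin, -3.42 ± 0.41 (adjusted p = 0.0388). Each of these 4 lost its call without any 1 of the 4 iLC and Leydig arrays, as did every gene called in this comparison. Mki67 differed by -0.23 and Tk1 by 0.14. The list's median was -2.83 (camera adjusted p = 1.45e-16; adjusted p = 0.322 with an estimated correlation). None of the 17 macrophage and leukocyte markers passed the test, and 2 were lower when adjusted over the list alone. Their median was -1.07 (camera adjusted p = 0.00515, or 0.664 with an estimated correlation). Lyz1, a lysozyme gene of that list, read 15534 on the MEF array and 1130 and 1865 on the iLC arrays. The macrophage median was -0.46 without iLC replicate 1, where the list's call was lost (adjusted p = 0.122), and -1.69 without iLC replicate 2. Cholesterol synthesis and uptake genes had a median of -1.42, with 0 of 17 past the test over all genes and 8 lower when adjusted over the list alone. Stard4 (-2.71) and Insig1 (-2.52) had its largest differences (camera adjusted p = 1.83e-05; adjusted p = 0.392 with an estimated correlation). Interferon response genes had a median of -1.01, with 0 of 19 past the test and 6 lower when adjusted over the list alone, among them Isg15 (-2.88) and Usp18 (-2.72) (camera adjusted p = 3.88e-05; adjusted p = 0.322 with an estimated correlation).

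Fibroblast and smooth muscle genes gave no call over all genes tested between iLC and MEF. The 18 fibroblast matrix genes had a median of -0.82 (camera adjusted p = 0.0367; adjusted p = 0.664 with an estimated correlation), with 2 lower when adjusted over the list alone. That call was lost without iLC replicate 2 (median -0.52, adjusted p = 0.312), with a floor at the 20th percentile and with the mean of a gene's probes. Col6a3 (-2.92) and the matricellular gene Postn (-2.66) had the largest differences. The 9 smooth muscle and peritubular myoid genes had a median of -1.21, with 5 lower when adjusted over the list alone, led by Lmod1 (-2.61) and Tagln (-2.24) (camera adjusted p = 0.000441; adjusted p = 0.296 with an estimated correlation). None of the 38 Hox genes passed (median 0.26), nor did any of the 8 reference genes (median -0.35), the 15 imprinted growth genes, where H19 differed by -4.10 (adjusted p = 0.0742), or the 19 germ cell markers (median 0.10). Krt19, a keratin, was the 1 epithelial marker called (-3.36, adjusted p = 0.0396). Its call, like every other in this comparison, was lost without any 1 of the 4 iLC and Leydig arrays.

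Over all genes, 53 were higher and 54 lower in iLC than in MEF at an adjusted p under 0.05, and 3005 had an unadjusted p under 0.05. The largest called differences on the higher side were those of Mrpl36 (8.82), Rchy1 (8.35), Atp5b (7.09), Gucy1a1 (6.88), a subunit of the nitric oxide receptor, N4bp1 (6.69), Defb45 (6.28), Dmbt1 (6.28), the gut peptide gene Pyy (6.18) and the alcohol dehydrogenase genes Adh1 (6.18) and Adh7 (6.15). Of these, Mrpl36, Rchy1, Atp5b and N4bp1 read between 49.1 and 69.5 on the MEF array, among its 74 dimmest probes, and 7476 or more on each of the other 4 arrays. On the lower side they were Shcbp1 (-4.56), Ifi27l2b (-4.56), Kif20b (-4.55), Wasf2 (-4.51), Kif23 (-4.46), Bub1 (-4.31), the skeletal actin gene Acta1 (-4.22), Hmmr (-4.20), Aspm (-4.13) and Cdkn3 (-4.12), of which Kif20b, Kif23, Bub1, Hmmr, Aspm and Cdkn3 act in cell division. Without any 1 of the 4 iLC and Leydig arrays, limma called 0 genes, with 2132 to 2886 at an unadjusted p under 0.05. Leaving out an array takes 1 of the 2 residual degrees of freedom, and without a Leydig array the iLC to MEF differences do not move at all. Without iLC replicate 1 or 2 the 28 named differences moved by at most 0.73, that of Hsd3b1 from 5.18 to 5.35 and 5.01. Centring each array on its median gave 130 higher and 209 lower, quantile normalization 164 and 201, and subtracting each array's low end, chosen after seeing the data, 6 and 0. The median over all genes was -0.11, and 0.05 after quantile normalization.

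**Figure D2:**
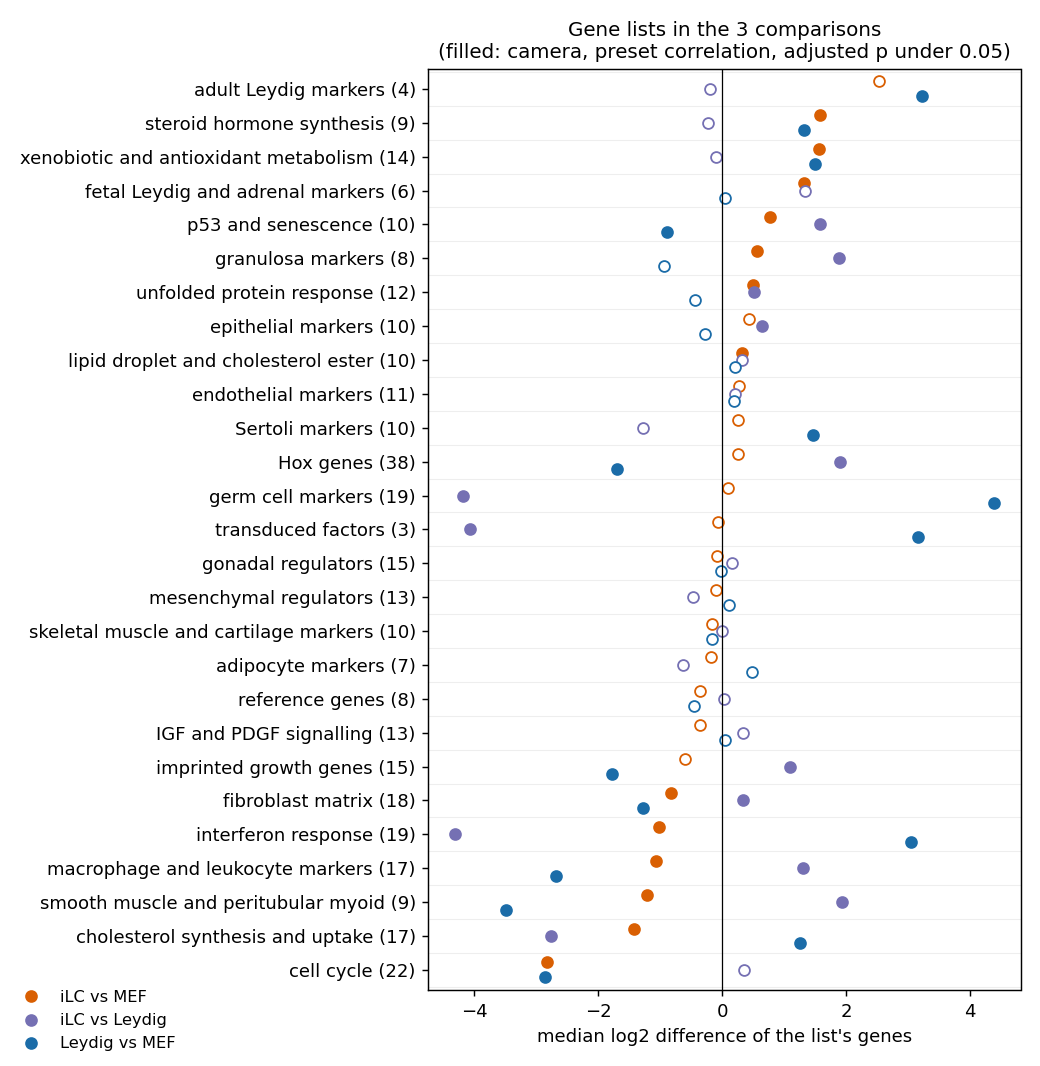
Median log2 difference (x axis) of each of 27 gene lists (y axis, number of measured genes in parentheses) for iLC against MEF (orange), iLC against Leydig (purple) and Leydig against MEF (blue). Filled points passed camera with the preset correlation, 41 of 81 tests, of which 0 passed with an estimated correlation; the cell cycle list lay at -2.83 against MEF and 0.35 against Leydig.

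The comparison of iLC with Leydig cells asked how far the arrays labelled iLC still lay from the cells they are named for. Some fibroblast genes read far above the Leydig level. Fn1, the fibronectin gene, read 169821 and 104543 on the iLC arrays and 1039 and 672.6 on the Leydig arrays (log2 difference 7.29 ± 0.40 SE, adjusted p = 0.001), and Lox, a collagen cross-linking enzyme, differed by 6.90 (adjusted p = 0.001). Of the 18 matrix genes 5 were higher and 1 lower, and 6 and 2 when adjusted over the list alone (median 0.34, camera adjusted p = 0.00769; adjusted p = 0.629 with an estimated correlation). Col6a3 was the lower gene (-2.80), and Sparc (0.20), Vim (0.27), Col6a1 (-1.45) and Dcn (-0.51), named after their values were seen, did not pass. The list's call was lost without iLC replicate 1 (median 0.52, adjusted p = 0.0504) or Leydig replicate 2 (0.27, adjusted p = 0.113), and its median was 0.93 without Leydig replicate 1. Smooth muscle genes were higher for 6 of 9, over all genes and over the list alone, including Tagln (6.18) and Acta2 (3.64) (median 1.94, camera adjusted p = 6.31e-06; adjusted p = 0.277 with an estimated correlation). Hox genes were higher for 20 of 38 and lower for 3, or 23 and 3 when adjusted over the list alone. Their median was 1.91 (camera adjusted p = 2.63e-09, or 0.277 with an estimated correlation), and it ranged from 0.78 to 2.12 over 19 alternatives. Hoxb8 differed by 4.44 and Hoxa11 by 3.92, and the 3 lower genes were Hoxd4 (-2.69), Hoxd8 (-1.66) and Hoxd9 (-2.74), while Hoxd11 and Hoxd12 were higher. Hoxd4 lost its call without Leydig replicate 2 (highest adjusted p = 0.054), Hoxd8 without any 1 of the 4 arrays (0.172) and Hoxd9 without iLC replicate 1 or either Leydig array (0.0551). Hoxd11 lost its call without iLC replicate 1 or either Leydig array (highest adjusted p = 0.17) and Hoxd12 without Leydig replicate 2 (0.0594). Among mesenchymal regulators 3 were higher, with Tbx15 at 7.25, and 3 lower, with Osr2 at -4.68, over all genes and over the list alone (median -0.47, camera adjusted p = 0.963).

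Of the steroid hormone genes Cyp17a1 and Hsd3b1 were lower in iLC than in Leydig cells and none was higher over all genes tested. Cyp17a1, the enzyme that commits steroids to androgen synthesis, read 1382 and 2351 in iLC and 40614 and 197728 in Leydig cells, a log2 difference of -5.62 ± 0.75 (SE, adjusted p = 0.00689). Hsd3b1 was lower by a difference of -2.24 (adjusted p = 0.0301), a call lost without any 1 of iLC replicate 1, iLC replicate 2 or Leydig replicate 1 (highest adjusted p = 0.14). Fdx1 (-0.25), Cyb5a (0.27), Tspo (-0.57), Cyp11a1 (0.61) and Hsd17b3 (-0.23) did not pass, nor did Star (3.63, adjusted p = 0.0984), Scarb1 (1.65, adjusted p = 0.0606), Hsd11b1 (-1.24, adjusted p = 0.0521), Sult1e1 (-0.15) or Ptgds (0.27). Of 9 steroid hormone genes 2 were lower over all genes, while 2 were higher and 2 lower over the list alone, and the list as a whole did not pass (median -0.23, or 0.28 without Leydig replicate 2, camera adjusted p = 0.963). Of the fetal Leydig and adrenal markers, Thbs2 (5.92), Cyp11b1 (4.05) and Mc2r (1.61) were higher and Mrap (-3.46) lower, 4 and 1 when adjusted over the list alone (median 1.34, camera adjusted p = 0.075). Mc2r lost its call without any 1 of the 4 arrays (highest adjusted p = 0.156) and Cyp11b1 without either iLC array (highest adjusted p = 0.0983). Among gonadal regulators Tcf21 (-8.45) and Nr2f2 (-2.19) were lower, and Emx2 (4.74), Gata6 (2.15) and Nr4a1 (2.05) higher, 2 and 3 over the list alone too (median 0.15, camera adjusted p = 0.586). Nr2f2 and Nr4a1 lost their calls without any 1 array (highest adjusted p = 0.092 and 0.12) and Gata6 without iLC replicate 2 or either Leydig array (highest adjusted p = 0.0744). Of 8 granulosa markers 4 were higher, among them Fst (4.42) and Inhba (4.11), and Inha was lower, over all genes and over the list alone (median 1.89, camera adjusted p = 0.00853; adjusted p = 0.52 with an estimated correlation). Fst, Inhba and Thbs2 did not pass between iLC and MEF (0.44, 0.29 and 0.72), the MEF array reading 10836, 18216 and 36514. The granulosa call was lost without iLC replicate 1 (adjusted p = 0.059) and with the stricter filter on dim genes.

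Cholesterol synthesis was lower in iLC than in Leydig cells. Of 17 genes, 12 were lower over all genes tested and 17 when adjusted over the list alone, none was higher, and the median was -2.75 (camera adjusted p = 2.13e-11; adjusted p = 0.322 with an estimated correlation). Cyp51, lanosterol demethylase, differed by -4.50 ± 0.39 (SE, adjusted p = 0.00194) and Idi1, isopentenyl diphosphate isomerase, by -3.83 ± 0.37 (adjusted p = 0.00246). Interferon response genes were lower for 17 of 19, and 18 when adjusted over the list alone (median -4.30, camera adjusted p = 1.45e-16; adjusted p = 0.277 with an estimated correlation), led by Mx1 (-6.46) and Gbp3 (-5.91). Of 10 p53 and senescence genes 6 were higher, and 8 when adjusted over the list alone (median 1.58, camera adjusted p = 4.03e-07; adjusted p = 0.277 with an estimated correlation), with Perp at 5.60, the insulin-like growth factor binding protein gene Igfbp3 at 5.51 and Cdkn2b, a cyclin-dependent kinase inhibitor, at 4.50. Imprinted growth genes were higher for 5 of 15, and 7 when adjusted over the list alone (median 1.09, camera adjusted p = 0.000288; adjusted p = 0.284 with an estimated correlation), led by Nnat (5.28). The unfolded protein response list had 3 of 12 members higher, and 5 when adjusted over the list alone (median 0.52, camera adjusted p = 0.0178; adjusted p = 0.323 with an estimated correlation), with Trib3 at 3.42 and Chac1 at 3.08; that call was also lost with the stricter filter on dim genes, the floor and aligned low ends. Of 14 xenobiotic and antioxidant genes 4 were lower, led by the retinaldehyde dehydrogenase gene Aldh1a1 (-4.69) and Gstm2 (-3.35), and 1 higher, over all genes and over the list alone (median -0.10, camera adjusted p = 0.416). The cell cycle list did not pass (median 0.35, camera adjusted p = 0.452). Its 1 called gene in limma, Cenpa, was higher (1.66, adjusted p = 0.0213), a call lost without any 1 of the 4 arrays.

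Some markers of other testis cells also differed between these arrays. Germ cell markers were lower in iLC for 9 of 19 genes and for 12 when adjusted over the list alone (median -4.17, camera adjusted p = 1.15e-06; adjusted p = 0.453 with an estimated correlation). Prm1, a protamine of maturing sperm, read 144.1 and 168.2 on the iLC arrays and 6235 and 141591 on Leydig replicates 1 and 2, and its call was lost without either iLC array (highest adjusted p = 0.0917). The list's median was -2.28 without Leydig replicate 2 and -7.39 without Leydig replicate 1. Of the Sertoli markers Aard (-4.21), Cldn11 (-2.82) and Clu (-2.51) were lower in iLC, 3 of 10 over all genes and over the list alone (median -1.27, camera adjusted p = 0.0569). Cldn11 lost its call without iLC replicate 1 or Leydig replicate 1 (highest adjusted p = 0.0655) and Clu without iLC replicate 1 or either Leydig array (highest adjusted p = 0.101). Macrophage markers were higher in iLC for 5 of 17 genes, and 8 when adjusted over the list alone, with 1 lower on both counts (median 1.30, camera adjusted p = 0.001; adjusted p = 0.629 with an estimated correlation), and the median was 0.69 without iLC replicate 2. The Fc receptor gene Fcgr3 (3.58) lost its call without either Leydig array (highest adjusted p = 0.0744), and the complement gene C1qb (3.53) without either iLC array or Leydig replicate 2 (highest adjusted p = 0.147).

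**Figure D3:**
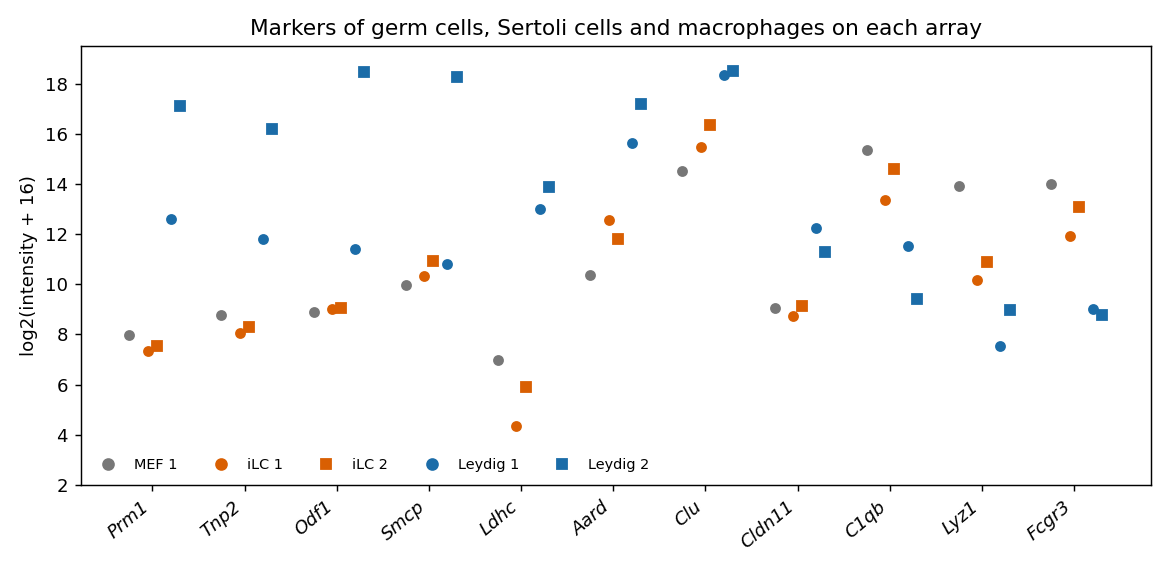
Markers of germ cells (Prm1, Tnp2, Odf1, Smcp, Ldhc) and Sertoli cells (Aard, Clu, Cldn11), and genes of the macrophage and leukocyte list (C1qb, Lyz1, Fcgr3). The y axis is log2 of intensity plus 16 on each of the 5 arrays. Circles are replicate 1, squares are replicate 2, and the genes shown were chosen after their values were seen. Odf1 read 2692 on Leydig replicate 1 and 356634 on replicate 2, while C1qb was highest on the MEF array at 41769.

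Over all genes, 1091 were higher and 1079 lower in iLC than in Leydig cells. The 10 largest called differences on the higher side were those of Ankrd1 (9.32), Col12a1 (8.61), Cthrc1 (8.41), Tnc (8.37), the prostaglandin synthase gene Ptgs2 (8.09), Olr1 (8.03), the cytokine gene Il6 (7.84), the neurofilament gene Nefm (7.79), Cck (7.33) and Fn1 (7.29). On the lower side they were Tcf21 (-8.45), the testis lactate dehydrogenase gene Ldhc (-8.32), Serpina5 (-8.31), Prm1 (-7.44), Cstdc2 (-7.44), Mmd2 (-7.39), the stem cell factor receptor gene Kit (-7.35), Crisp2 (-7.31), the angiotensinogen gene Agt (-7.00) and Itih5 (-6.81). Of these 20 genes, Prm1 and Crisp2 lost their calls without either iLC array (highest adjusted p = 0.0917 and 0.128). The counts fell to 556 higher and 412 lower without iLC replicate 1, 485 and 537 without iLC replicate 2, 508 and 763 without Leydig replicate 1, and 334 and 362 without Leydig replicate 2.

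Leydig cells and MEF were compared to give the distance between the starting cells and the reference cells. Hsd3b1 (7.42), Cyp17a1 (5.25) and Fdx1 (3.78) were higher in Leydig cells, 3 of the 9 steroid hormone genes and 4 when adjusted over the list alone (median 1.32, camera adjusted p = 0.000141; adjusted p = 0.284 with an estimated correlation). Nr5a1 was higher by 5.43 ± 0.44 (SE, adjusted p = 0.00338) and Gata4 by 3.16 ± 0.43 (adjusted p = 0.0111), the latter not without either Leydig array (highest adjusted p = 0.0641). Cyp17a1 and Fdx1 lost their calls without Leydig replicate 2 (highest adjusted p = 0.0664 and 0.0551). Interferon genes were higher for 11 of 19, and 16 when adjusted over the list alone (median 3.04, camera adjusted p = 4.19e-15; adjusted p = 0.277 with an estimated correlation). Cell cycle genes were lower for 13 of 22, and 19 when adjusted over the list alone (median -2.85, camera adjusted p = 1.07e-13; adjusted p = 0.323 with an estimated correlation), smooth muscle genes for 7 of 9, and 9 (median -3.48, camera adjusted p = 2.84e-09; adjusted p = 0.277 with an estimated correlation) and macrophage markers for 9 of 17, and 12, with 1 higher over the list alone (median -2.67, camera adjusted p = 7.12e-06; adjusted p = 0.52 with an estimated correlation). Some markers of other testis cells were also higher on the Leydig arrays. Germ cell markers had positive differences for 19 of 19, of which 3 passed, and 8 when adjusted over the list alone (median 4.38, or 2.15 without Leydig replicate 2, camera adjusted p = 2.93e-08; adjusted p = 0.404 with an estimated correlation). Of 10 Sertoli markers 3 were higher, over all genes and over the list alone (median 1.46, camera adjusted p = 0.00769; adjusted p = 0.322 with an estimated correlation). The 3 largest called differences were those of Defb19 (9.12), Mrpl36 (8.74), which read 49.1 on the MEF array and was among its 4 dimmest probes, and Mmd2 (8.67) on the higher side and Ankrd1 (-9.33), Col12a1 (-9.33) and Postn (-8.93) on the lower side. In all, 637 genes were higher and 757 lower. These counts were 429 and 535 without either iLC array, 381 and 310 without Leydig replicate 1, and 79 and 74 without Leydig replicate 2.

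The position of iLC between these groups was read from the 1394 genes called between Leydig cells and MEF. Between iLC and MEF, 71 of them were called in the same direction, 3 in the opposite direction and 1320 not at all, while 923, or 66.2%, were still called between iLC and Leydig cells. The 21 genes higher in both iLC and Leydig cells included Hsd3b1, Fdx1, Mrap, Abca1, Gsta3, Defb19 and Adh1, and also Mrpl36, Rchy1, Atp5b and N4bp1, which were near the lowest values on the MEF array. Leaving out the genes dark on 1 array, chosen after seeing the data, gave 65 in place of 71. The 1394 genes rest on Leydig arrays on which 3 of 19 germ cell and 3 of 10 Sertoli markers were called higher than in MEF. The 50 genes lower in both included Aurka, Plk1, Foxm1, Kif23, Acta1 and Col8a1. Foxm1, Plk1 and Col8a1 were picked after their values were seen. The 3 opposite genes were Il6, Mapk13 and 4930486L24Rik, higher in iLC and lower in Leydig cells than in MEF. Arrays of iLC were simulated 50 times with no change from MEF, sharing the same MEF value. They gave 0.04 genes called in the same direction on average (0 to 1). No gene truly differed between simulated iLC and MEF, so hardly any such call could arise. The contrast with 71 therefore cannot by itself show a shift towards Leydig cells. Independent lists of the observed lengths would share 1.77 higher and 2.14 lower genes. Across genes, which are not independent replicates, the log2 differences of iLC and of Leydig cells from MEF correlated at 0.387 with a covariance of 0.448, against 0.293 and 0.249 in the simulation. Both comparisons use the same single MEF array, which cannot be split, so part of the excess may come from it. The median share of the Leydig-to-MEF difference seen in iLC was 0.144 for genes higher in Leydig cells and 0.323 for genes lower, against 0.0533 and 0.0676 in the simulation, where 2480 genes on average were called between Leydig cells and MEF. Of the simulated genes called between Leydig cells and MEF, 89.2% (87.8 to 90.7) were also called between iLC and Leydig cells, against 66.2% here. The count of 71 was 0 without any 1 of the 4 iLC and Leydig arrays, with 2132 to 2886 genes at an unadjusted p under 0.05 between iLC and MEF in limma.

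**Figure D4:**
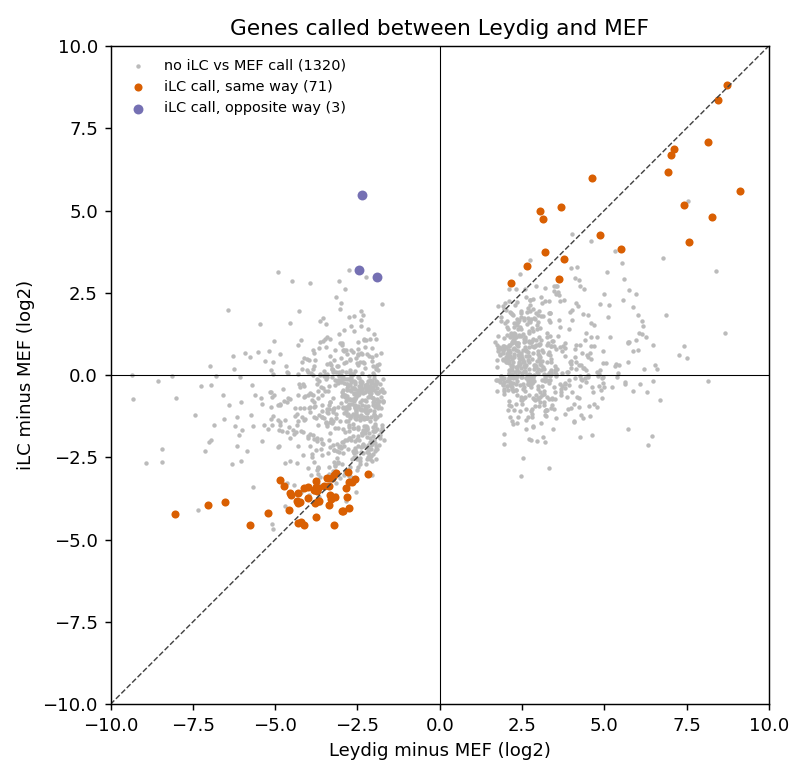
Log2 difference of iLC from MEF (y axis) against that of Leydig cells from MEF (x axis) for the 1394 genes called between Leydig cells and MEF; the dashed line marks equal differences. Orange points are the 71 genes called in the same direction between iLC and MEF, purple points the 3 called in the opposite direction, and grey points the 1320 with no such call; both axes share the MEF array.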

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

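The 4547 probes without a gene name took no part in the comparisons and were fitted by themselves with the same limma model. Between Leydig cells and MEF, 13 of them were higher and 9 lower, with a largest difference of -7.35 on the log2 scale. Between iLC and Leydig cells, 36 were higher and 39 lower, with a largest difference of -8.45. Between iLC and MEF, 0 passed in either direction. What these probes measure was not examined.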

How the results depend on the processing

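No called gene named by the rule fixed beforehand and no gene list called by camera changed direction under any alternative tried. Direction could not change under several of these, such as the intensity trend, the robust prior and the other list tests, which leave the log2 differences as they are. Between iLC and MEF this also holds without a Leydig array. The filters on dim genes kept 263 and 202 of 281 named results. Of all called genes, 2 changed sign between Leydig cells and MEF after quantile normalization, and 3 and 1 between iLC and Leydig cells with the floor and with the mean of probes. Genes named after their values were seen were not followed one by one. The count of genes called between iLC and MEF (53 higher and 54 lower) was the least stable. It was 164 and 201 after quantile normalization, 130 and 209 with each array centred on its median, 124 and 141 with the milder filter on dim genes, 240 and 179 with the stricter one, 117 and 136 with an intensity trend, and 0 and 0 with a floor at the 20th percentile. Among alternatives chosen after seeing the data it was 85 lower with a larger added value, 6 and 0 with low ends aligned, and 0 and 0 with only the 3 MEF and iLC arrays, where 2886 genes had an unadjusted p under 0.05 in limma. It ranged from 0 to 0 in both directions when 1 of the 4 iLC and Leydig arrays was left out. The floor made 1852 genes exactly equal within both pairs and lowered the prior degrees of freedom from 4.21 to 0.598; 2989 genes still had an unadjusted p under 0.05 between iLC and MEF. Leaving an array out leaves 1 residual degree of freedom fewer. The prior degrees of freedom moved in other settings too. They were 2.57 with low ends aligned, where 55 genes were exactly equal within both pairs. With quantile normalization, centring and the stricter filter they were 5.24, 6.07 and 8.44. The larger added value had 3.14 and still gave more calls than the main fit, 63 higher and 85 lower. For these other changes the cause was not tested.

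Between iLC and Leydig cells the floor gave 194 higher and 175 lower. Leaving out 1 array gave 334 to 556 higher and 362 to 763 lower. The replicate numbers do not pair the samples: deviations of iLC and Leydig arrays with the same number correlated at 0.0557 across genes. With a replicate block on the 4 arrays, 1482 genes were higher and 1958 lower, and 95 of 95 named calls stayed. The prior degrees of freedom were infinite in that fit, against 4.21 in the main fit, so every gene was given the same spread. Its counts and kept calls are therefore no check of stability. The replicate block ended 1 list call, that of the epithelial markers. With only these 4 arrays the counts did not move, and they could not, since the lone MEF array adds nothing to the estimated spread. Between Leydig cells and MEF the floor gave 70 higher and 115 lower, and leaving out 1 array 79 to 429 higher and 74 to 535 lower. Leydig against MEF had 937 genes higher after quantile normalization.

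The 71 genes called in the same direction in iLC and Leydig cells against MEF became 216 after quantile normalization, 201 with centring, 158 and 225 with the filters, 154 with the trend, 0 with the floor, 5 with low ends aligned, and 0 to 0 without 1 of the 4 arrays. Of 41 list calls, 0 held in camera with an estimated correlation, and with fry 27 held and 14 were lost, among them the cholesterol, interferon, granulosa, matrix and macrophage lists between iLC and MEF. Of the named genes called, 28 of 28 between iLC and MEF lost their calls without at least 1 array, 35 of 95 between iLC and Leydig cells and 50 of 87 between Leydig cells and MEF. Star between iLC and MEF passed under 2 of 16 alternatives, with adjusted p from 0.0094 to 0.346 and log2 differences from 5.33 to 6.70; Hsd3b1 passed under 9 of 16 (0.00055 to 0.172). No signal over background was used, so what limits dim genes is known only from the low ends of the arrays.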

Other observations

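The tests of explanations below were all chosen after the results were seen. A further group of genes set iLC apart from both other groups. Called higher in iLC than in both MEF and Leydig cells were 33 genes. Independent lists gave 3.03 and simulated unchanged iLC 0.04. Unchanged iLC can hardly have calls against MEF, so the simulated counts are near 0 by design and measure no excess. Both comparisons share the iLC arrays, so part of the excess over independent lists may come from them. The same holds for the 4 genes below both (3.05 for independent lists and 0 in the simulation). The 33 included the neurofilament genes Nefl (5.88 above MEF and 6.15 above Leydig cells) and Nefm (5.45 and 7.79), the peptide genes Pyy (6.18 and 7.14), Gal (4.79 and 4.53), Adcyap1 (3.85 and 3.94) and Nppc (3.19 and 3.26), the endothelin gene Edn2 (5.12 and 6.30), the cytokine genes Il6 (5.47 and 7.84), Tnfsf11 (3.99 and 5.10) and Ccl17 (5.03 and 4.34), and Wnt2 (3.93 and 4.04). These were picked from the 33 after their values were seen. Below both lay Ccl3 (-3.42 and -2.39), Cd72, Hells and Slamf9. With any 1 of the 4 iLC and Leydig arrays left out, limma called 0 genes between iLC and MEF.

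Families of genes that share the opening letters of their symbols were tested by Fisher's exact test among all genes tested, 319 families in 1914 tests with Benjamini-Hochberg adjustment. Genes of a family are not independent, so these values describe. Kinesin genes (Kif) made up 6 of the genes lower in iLC than in MEF, where 0.105 were expected (adjusted p = 8.02e-07), and 10 of those lower in Leydig cells than in MEF (adjusted p = 0.000327). Aldehyde dehydrogenase genes (Aldh) were higher in Leydig cells than in MEF for 9 of 19 (adjusted p = 2.12e-06) and lower in iLC than in Leydig cells for 9 (adjusted p = 0.000101), led by Aldh1a1. The integrin alpha genes (Itga) were lower in Leydig cells than in MEF for 6 of 12 (adjusted p = 0.000688). Among lists not described so far, between iLC and Leydig cells 4 of the 13 IGF and PDGF signalling genes were higher, led by Igfbp5 (6.86), and 4 lower, led by Igfbp6 (-3.99), or 5 and 4 when adjusted over the list alone, with a median of 0.34 (camera adjusted p = 0.708). Of endothelial markers Flt1 (2.97) and Esam (1.53) were higher and Cdh5 (-2.76) lower, and Fabp4 (3.21) was the 1 adipocyte marker called. Flt1 lost its call without either Leydig array, Esam without any 1 array and Fabp4 without either iLC array or Leydig replicate 1 (highest adjusted p = 0.0661, 0.135 and 0.159).

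Germ cell transcripts stood far higher on Leydig replicate 2 than on replicate 1, with a median log2 difference of 3.32 over 19 markers. The central 95% of 10000 random lists of like brightness ran from -0.32 to 0.32. Their genes were drawn singly, so that range leaves out the correlation among germ cell genes and is no test. Smcp read 1800 and 313236, and Oaz3 3240 and 397097. A difference in scale is argued against by the reference genes, whose median differed by 0.272. A sample without the transcripts of replicate 1 is argued against too, since 99 of the 100 genes most above MEF on replicate 1 were at least 2-fold above MEF on replicate 2, against 48 and 45 on the iLC arrays, which share the MEF array. RNA from germ cells in that preparation stays open as a candidate source: a separate list of 36 spermatid genes had a median difference of 1.75. That list extends the pattern to further germ cell genes and does not tell its source. Not all members went this way. Of the markers fixed beforehand Ddx4 (-0.02), Dazl (-0.397) and Tex101 (-0.601) were lower on replicate 2, as were 4 of the 36 spermatid genes, Capza3 (-2.95) most. Genes of the steroid hormone and adult Leydig lists also differed between replicates 1 and 2, in both directions, and the germ cell lists do not cover them. Star read 1368 and 19703 and Ptgds 2214 and 235608, while Hsd3b1 read 218338 and 95740 and Scarb1 61600 and 37023. These were picked after their values were seen. No other explanation was tested.

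Atp5b, Mrpl36, N4bp1 and Rchy1 were in the lowest hundredth of the MEF array and in the upper part of the other 4, and they were 4 of the 5 genes with the largest called differences higher in iLC, with Gucy1a1. No such gene was found on 3 of the other arrays and 1 on Leydig replicate 2. Low levels of mitochondrial ribosome and ATP synthase transcripts as a class in MEF are argued against by the other 83 genes of the Mrpl, Mrps and Atp5 families, with a median iLC to MEF difference of -0.0803, which says nothing of N4bp1 and Rchy1. Spots without signal on the MEF array stay open and cannot be told apart from low transcripts of these 4 genes, because 0 other named probes measure them and there is 1 MEF array.

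Cell cycle transcripts had negative iLC to MEF differences for 21 of 22 genes, of which 6 passed over all genes tested. Their median was -2.83, against -0.34 to 0.33 for the central 95% of random lists of like brightness. Genes of the random lists were drawn singly. The range therefore leaves out the correlation among cell cycle genes and the spread between samples, and it is no test. A difference in scale or low end between arrays is argued against, since the median nearest to 0 under quantile normalization, centring and aligned low ends was -2.82. The calls of single genes ended with aligned low ends, where 0 genes were lower, while the list's median was then -2.83. The MEF array standing apart by itself cannot be told apart from a change in iLC. The list's median between iLC and Leydig cells was 0.348, so the 4 other arrays lay together by that median, though Cenpa was called higher in iLC. No second MEF array exists in these data. The delivered factors stay open as an explanation and were not tested. Whether iLC and MEF also differed in medium or culture time is not given, so these cannot be told apart from the factors.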
